A study of Mus musculus with 27 samples.

How the data were processed

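The data are RNA-seq libraries of mouse type 1 conventional dendritic cells (cDC1s), the dendritic cell subset that takes up dead cells and presents their antigens to CD8 T cells. Per the labels' protocols, bone marrow was cultured with 50 ng/mL Flt3L and 2 ng/mL GM-CSF, replated on day 9 and sorted by flow cytometry on days 15 to 17 as CD11c+, CD45R−, CD24+, CD172α− and CD103+ cells. The marrow came from C57BL/6J wild-type mice, from a knockout of the classical MHC class I genes H2-K1 and H2-D1 (MHC-I KO), or from a deletion of the MHC class II gene cluster (MHC-II KO). Sorted cells were left unstimulated or were stimulated for 16 h with 20 µg/mL poly dI:dC, a synthetic double-stranded nucleic acid, in 20 ng/mL GM-CSF, with or without 20 µg/mL of an agonistic antibody to CD40 (αCD40). CD40 is the receptor through which helper T cells activate dendritic cells. The sample titles abbreviate the stimulus PIC, and the treatment label names it poly dI:dC, which is the name used here. The labels do not say whether unstimulated cells were kept in culture for the 16 h or in the higher GM-CSF concentration, so a difference from unstimulated cells covers the whole handling of the stimulated ones. The 3 genotypes and 3 treatments make 9 groups of 3 libraries, 27 in all. Both knockouts carry strain names of 129-derived embryonic stem cells, and genotype was not crossed with any recorded culture, animal or sort day.

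Per the labels' protocols, polyadenylated RNA was sequenced as 150 bp paired-end reads on a NovaSeq X-Plus. The submitters' processing notes name STAR, RSEM and the mouse genome build GRCm39; the versions, the annotation, the filters and whether reads were counted by strand are not given in the sources used here. The table deposited by the authors holds RSEM expected counts per gene, which are estimated counts that share reads between similar genes in proportion to a model. Of the values, 4.757% are not whole. The table lists 57186 genes, of which 32320 are at 0 in every library and 535 have no symbol. Class I genes and their near-identical relatives can exchange reads under such a model, so the values of single class I genes, H2-K1 in the knockout included, are uncertain. Genes that overlap, or lie antisense to each other, could not be told apart either.

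Expected counts were rounded to whole numbers. Genes were kept with the filterByExpr function of edgeR by group, which left 14370, and libraries were scaled with the trimmed mean of M-values (TMM). A single quasi-likelihood model (edgeR 4.0.16, in R 4.3.3) was fitted with 1 coefficient for each of the 9 groups and no other term, so that all groups share 1 estimate of the spread. Its prior degrees of freedom were 11.25 and the common biological coefficient of variation was 29.71%. The 22 comparisons were contrasts of this model, and 4 of them were interactions, which test the difference between the responses of 2 genotypes. A gene was called at an edgeR adjusted p under 0.05 (Benjamini-Hochberg over the genes of a comparison, two-sided). Log2 fold changes are given ± SE from this model. Levels are CPM on the TMM-scaled library size, given as mean ± SD of 3 libraries.

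Lists of genes were fixed by name: cDC1 identity (22 genes), interferon-stimulated genes (40), dendritic cell maturation and migration (28), cytokines and chemokines (32), T cell costimulatory ligands (16), T cell inhibitory ligands and enzymes (20), MHC class I molecules (18), MHC class I processing and loading (18), MHC class II molecules and processing (22), NF-κB pathway and targets (27), nucleic acid sensing (25), cross-presentation and uptake (20), cell cycle (34), apoptosis and survival (26), glycolysis (20), oxidative phosphorylation (32), cholesterol synthesis (21), immediate early and heat shock genes (23), and the unfolded protein and integrated stress response (19). Lists for other cells that the gate could hold were cDC2 (15), plasmacytoid dendritic cells (15), monocytes and macrophages (18), neutrophils (15), B cells (10), T and NK cells (15), mast cells and basophils (12), erythroid cells (12) and stromal cells (10), with 6 sex-linked check genes. Cd58 and the older symbols Atp5a1 and Atp5b are not among the gene names of the table. Each list was compared with all other genes by limma 3.58.1 camera on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The estimated correlation and fry were alternatives. The lists overlap, with 21 genes in more than 1 list, so their calls are not separate evidence. The maturation list shares 4 genes each with the NF-κB and costimulatory lists, the interferon list 5 with nucleic acid sensing, and the cDC1 list 4 with cross-presentation. The groups, the tests, the lists, the rule for named genes and all but the last 4 of the other settings named here were set before the data were examined.

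The genes named singly follow that rule. They are the targeted genes, and in each comparison of 2 groups the 6 called genes with the largest log2 fold change each way among those with a mean of at least 5 CPM and no overlap between the libraries, and 5 each way in an interaction. Predicted genes, immunoglobulin and T cell receptor segments and pseudogenes were left out, and a few genes that the rule names are not reported here. From each list described, up to 4 members with the smallest p and up to 2 called against the list's direction are named. Btnl2 in the MHC-II KO and further members of a list beyond these were chosen after their values were seen. Where a group had 0 counts for a gene, the fold is a lower bound against 3 counts over the group's libraries. With 1 to 3 counts the ratio is given with its exact 95% interval (Clopper-Pearson, on the summed counts). These intervals and bounds cover counting error only.

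Positions come from GENCODE M21 (GRCm38), matched by Ensembl identifier for 14021 of the tested genes, while the counts were made on GRCm39. Called genotype differences within 10 Mb of the H2-K1 to H2-D1 span were compared with the rest of the genome by Fisher's exact test (two-sided). Comparisons of the 2 knockouts with the same wild-type libraries share their chance values. So 20 sets were simulated in which the libraries of all genotypes, wild-type included, were drawn from the wild-type means of their treatment. Replicates were checked for duplicates by a chi-square test on genes with at least 20 counts in a pair, and for pairing by number over the 500 genes that varied most. In simulated counts for the unstimulated MHC-I KO against wild-type, 50% of 100 genes changed 2-fold and 72% of 100 changed 4-fold were called, with 5 unchanged genes called among 13339 (3.94% of the calls). For the interaction of the MHC-I KO with poly dI:dC the shares were 36% and 64%, with 7 unchanged genes called among 13340. Of 100 unchanged lists of 40 genes, 1 had an unadjusted camera p under 0.05, and a list raised by 0.5 on the log2 scale ranked 1. Co-regulated genes, and so the preset correlation, were not tested.

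Other settings tried were median-of-ratios (RLE) size factors, no filter on low counts, a minimum of 1 CPM in 3 libraries, a fit with the replicate number as a block, a fit of only the compared groups, DESeq2 1.42.0, and each library left out in turn. Scaling by library size alone, counts of list members without replicate 3 of the MHC-II KO with poly dI:dC, and list tests without the deleted genes or without genes of more than 1 list, were chosen after seeing the data. No library was left out of the main results.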

Results

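Gene expression was measured by RNA-seq in sorted cDC1s grown from bone marrow of wild-type, MHC-I KO and MHC-II KO mice, each unstimulated, with poly dI:dC, or with poly dI:dC plus αCD40. The series concerns which antigen presentation by cDC1s is needed when these cells are given as a cancer immunotherapy, so the groups ask how cDC1s without class I or class II molecules differ at rest and how they respond to the same activation. Each of the 9 groups had 3 libraries, with total counts from 15485019 to 26066962 per library. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. No pair of replicates agreed within sampling noise (chi-square per degree of freedom from 6.47 to 39.03), and all were counted separately.

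Stimulation set the largest difference between libraries. The first principal component of the 1000 most variable genes held 55.7% of the variance and parted unstimulated from stimulated libraries, and the second held 7.99%. In wild-type cells the 50 most abundant genes took 19.1% of the counts at rest and 22.4% with poly dI:dC, and in MHC-I KO cells 20.2% and 24.1%. Mean TMM factors fell with stimulation from 1.31 to 0.97 in wild-type, from 1.24 to 0.80 in MHC-I KO and from 1.32 to 0.91 in MHC-II KO cells. Mitochondrial genes took between 0.97% and 1.48% of the counts in the means of the groups, and in unstimulated cells 0.972% ± 0.023 in wild-type, 1.02% ± 0.19 in MHC-I KO and 1.48% ± 0.12 in MHC-II KO (SD, n = 3). Xist, the transcript of the inactive X chromosome of female cells, had 0 counts in every library. Of the MHC-II KO libraries with poly dI:dC, replicate 3 had counts for 16070 genes against 13034 and 14006 in replicates 1 and 2.

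**Figure D1:**
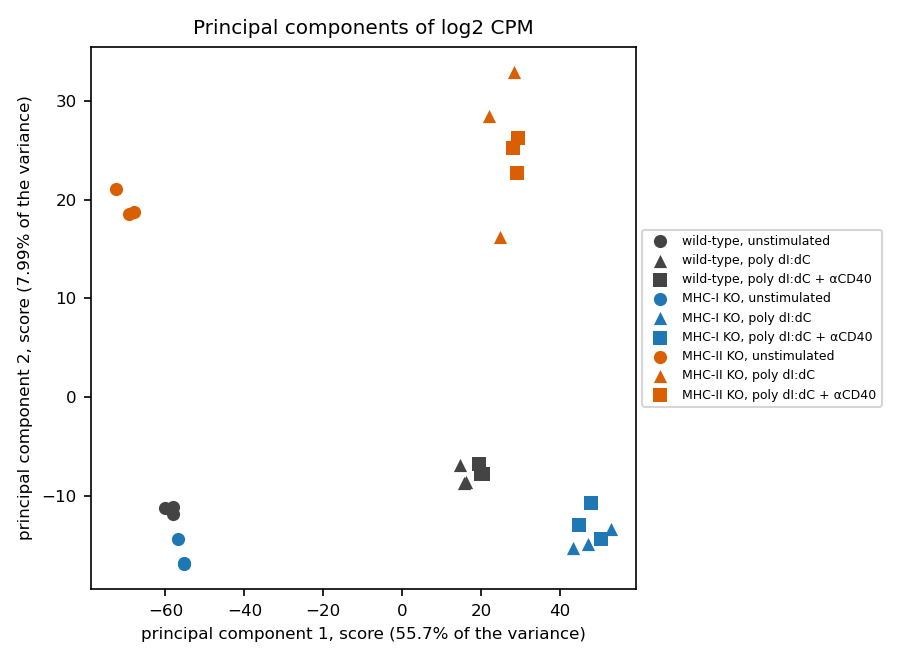
Libraries are plotted on the first and second principal components of log2 CPM over the 1000 most variable genes, with colour for genotype and symbol for treatment. The first component (55.7% of the variance) parts unstimulated from stimulated libraries, and the second holds 7.99%.

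The targeted genes followed the labels in every library. H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499 in GRCm38), a classical class I molecule, stood at 1280 ± 46.7 CPM in unstimulated wild-type cells (SD, n = 3) and had 0 counts in unstimulated MHC-I KO cells, at least 28800-fold lower. It had, with poly dI:dC, 3 counts over the 3 MHC-I KO libraries, which is 0.00232% of wild-type (exact 95% interval 0.000479 to 0.00678), and with αCD40 added 0 counts, at least 39100-fold lower. H2-K1 (ENSMUSG00000061232, 33996017 to 34000347), the other classical class I molecule of this strain, kept 141.2 ± 17.7 CPM at rest in MHC-I KO against 1361 ± 44.1 CPM in wild-type cells, or 10.3% of wild-type. It kept 14% with poly dI:dC and 15.3% with αCD40 added. Reads shared with other class I genes make these remainders uncertain. In MHC-II KO cells H2-K1 (1221 CPM) and H2-D1 (1167 CPM) were present at rest.

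In MHC-II KO cells the genes of the class II α and β chains were missing. H2-Aa (34282744 to 34287823) had 5811 ± 81.5 CPM in unstimulated wild-type cells and 0 counts in unstimulated MHC-II KO cells, at least 159000-fold lower. H2-Eb1 (34305867 to 34316674) had 6478 ± 87.2 CPM in wild-type and 0 counts in these knockout cells, at least 177000-fold lower. H2-Eb2 (34325665 to 34341412) had 45.86 ± 3.22 CPM in wild-type cells at rest and 0 counts in MHC-II KO cells under each treatment, at least 1260-fold lower at rest. H2-Ab1 (34257689 to 34269419) kept 23.51 ± 9.21 CPM against 6802 ± 169 CPM, or 0.366% of wild-type by summed counts, and 0.423% with poly dI:dC. In the libraries with poly dI:dC, all 24 counts of H2-Aa and all 26 of H2-Eb1 came from replicate 3, and both genes were at 0 in replicates 1 and 2 and with αCD40 added. H2-Ea (34341959 to 34344645), which is not expressed in the C57BL/6 strain, reached at most 0.3042 CPM in the mean of any group. H2-Aa was present in MHC-I KO cells (6910 CPM at rest).

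**Figure D2:**
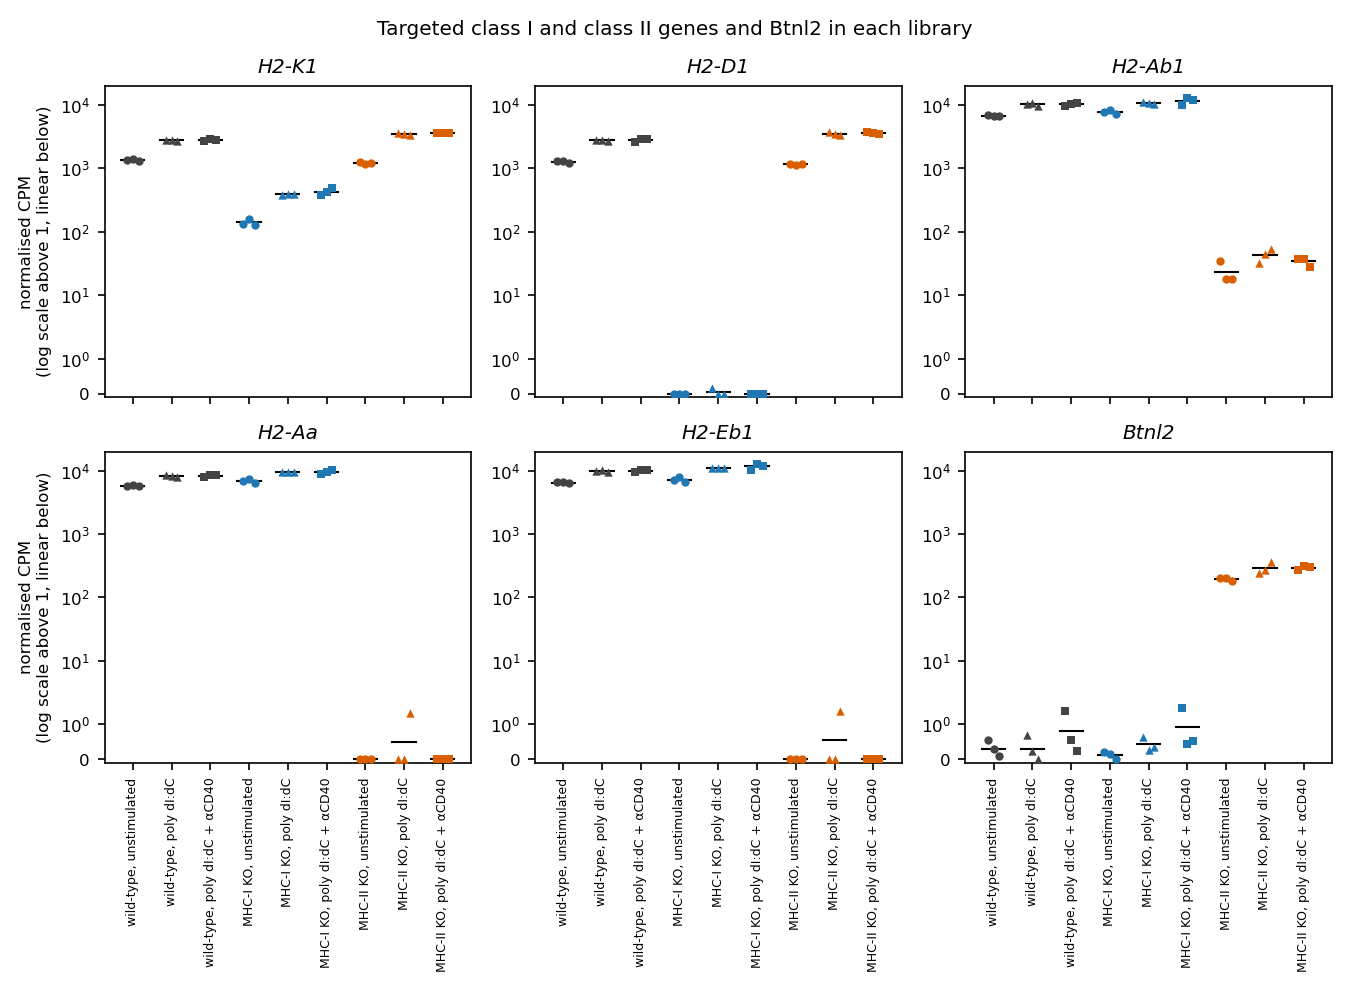
CPM of the targeted class I and class II genes is shown for each library by genotype and treatment, on a logarithmic axis that marks 0 separately. H2-D1 is at 0 counts in 2 of the 3 MHC-I KO groups, while H2-K1 keeps 10.3% to 15.3% of the wild-type level.

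Scaling by library size alone lowered the median log2 fold change of all genes by −0.43 for poly dI:dC in wild-type cells, −0.63 in MHC-I KO and −0.55 in MHC-II KO cells, and the changes given here are relative to the TMM scale. Under it the share of higher genes among those called fell from 54.7% to 23.3%, from 47.3% to 21.5% and from 50.8% to 23.4%. With αCD40 added the shifts were −0.45, −0.67 and −0.57, and the shares moved from 52.9% to 22.7%, from 48% to 20.9% and from 49.7% to 23.5%.

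The comparison of wild-type cDC1s with and without poly dI:dC asks what activation by a nucleic acid does to normal cDC1s. Genes for chemokines rose most: Ccl4, which attracts T cells and NK cells, went from 0.523 to 105 CPM. Ccl3 rose 35.3-fold and Cxcl10, a ligand of CXCR3 on activated T cells, 38.6-fold. Tnfsf15, a TNF family ligand, rose 42.3-fold and the Notch ligand Dll4 39.4-fold. Falling genes included Cxcr3 itself (15.8 to 0.612 CPM), the lysophosphatidic acid receptor gene Lpar5 (47.7-fold) and the amino acid transporter gene Slc43a2 (38.3-fold). Others were the lysosomal sulfamidase gene Sgsh (31.1-fold) and the mitochondrial acetate-activating enzyme gene Acss1 (25.7-fold). Abhd15 had 10.8 CPM at rest and 0 counts with poly dI:dC, at least 182-fold lower. In all, 5396 of 14370 genes were called (edgeR, adjusted p under 0.05), 2950 higher and 2446 lower.

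All 40 interferon-stimulated genes rose in wild-type cells (40 adjusted over the list alone, median log2 fold change 2.15, limma camera adjusted p = 2.37e-37, and 0.000251 with an estimated correlation for the 35 in no other list). Among them were the antiviral genes Oasl1 (3.18 ± 0.07) and Rsad2 (4.28 ± 0.11) and the guanylate-binding protein gene Gbp5 (3.66 ± 0.11). Of 27 maturation and migration genes 25 rose and none fell (25 and 0 adjusted over the list alone, adjusted p = 1.78e-26), including the adhesion molecule gene Icam1 (2.06 ± 0.05), Cd40 (3.08 ± 0.09) and Traf1 (2.17 ± 0.06). All 27 NF-κB genes rose (27 adjusted over the list alone, adjusted p = 8.6e-33), led by Nfkbiz (4.03 ± 0.12). Among 29 cytokines and chemokines 21 rose, none fell and 8 were not called (21 and 1 adjusted over the list alone, adjusted p = 9.1e-12). Il12b, a subunit of IL-12 that drives type 1 T cell responses, rose by 3.21 ± 0.06, and Tnf by 4.49 ± 0.14. Costimulatory ligands for T cells rose in 10 of 15 and fell in 3 (10 and 3 adjusted over the list alone, adjusted p = 6.28e-05, and 0.159 for the 11 members in no other list). Tnfsf9, the ligand of 4-1BB, stood at 3.68 ± 0.12, Cd86 at 1.65 ± 0.07 and Cd48 at −2.11 ± 0.15. Inhibitory ligands and enzymes rose in 13 of 17 and fell in 2 (13 and 3 adjusted over the list alone, adjusted p = 1.18e-07). Cd274, which encodes PD-L1, rose by 2.11 ± 0.07 and the tryptophan-degrading enzyme gene Ido1 by 3.38 ± 0.13, and Havcr2, which encodes TIM-3, stood at −0.28 ± 0.08.

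Class I molecules rose in 11 of 14 with none lower (11 adjusted over the list alone, adjusted p = 8.75e-08), H2-K1 by 1.03 ± 0.07 and H2-Q7 by 1.57 ± 0.12. Class I processing and loading genes rose in 16 of 18 with none lower (16 adjusted over the list alone, adjusted p = 6.87e-13), such as the peptide transporter gene Tap1 (1.03 ± 0.06). Class II genes rose in 11 of 21 and fell in 5 (11 and 5 adjusted over the list alone, adjusted p = 0.0122, and adjusted p = 0.182 with an estimated correlation). With library-size scaling 5 were higher and 10 lower. The invariant chain gene Cd74 stood at 0.72 ± 0.06 and the class II transactivator gene Ciita at 0.85 ± 0.08, against Marchf1, a ligase that removes class II from the surface, at −0.74 ± 0.12. Cross-presentation and uptake genes rose in 10 of 20 and fell in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.00591), with Axl at 1.93 ± 0.05 and the dead-cell receptor gene Clec9a at −0.63 ± 0.07. Their median of 0.42 turned to −0.02 with library-size scaling. Nucleic acid sensors rose in 16 of 24 and fell in 5 (16 and 6 adjusted over the list alone, adjusted p = 2.51e-07). Ifih1, a cytosolic RNA sensor gene, rose by 2.25 ± 0.08, and Tlr3, the endosomal double-stranded RNA receptor of cDC1s, stood at −2.33 ± 0.15. The cDC1 identity list fell (14 of 22 lower, 3 higher; 15 and 3 adjusted over the list alone, adjusted p = 1.8e-05). Itgae, which encodes the CD103 of the sort, stood at −1.91 ± 0.10, while Ly75 (1.82 ± 0.10) and Xcr1 (0.40 ± 0.06) were higher.

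The unfolded protein and integrated stress response also rose in 16 of 19 with none lower (18 adjusted over the list alone, adjusted p = 5.06e-10), with the endoplasmic reticulum chaperone genes Hspa5 at 1.59 ± 0.05 and Hsp90b1 at 1.15 ± 0.06. Cholesterol synthesis rose in 17 of 20 (18 higher and 1 lower adjusted over the list alone, adjusted p = 2.09e-10; Hmgcs1 1.43 ± 0.06). Glycolysis genes rose in 15 of 20 with 1 lower (15 and 1 adjusted over the list alone, adjusted p = 3.86e-10; Pfkfb3 1.53 ± 0.06). Apoptosis and survival genes rose in 16 of 26 with 3 lower (16 and 4 adjusted over the list alone, adjusted p = 3.09e-07; Bcl2l1 2.90 ± 0.09, Bid −0.90 ± 0.28). Immediate early and heat shock genes rose in 14 of 23 with 7 lower (14 and 7 adjusted over the list alone, adjusted p = 0.000105; Nr4a3 2.68 ± 0.07, Egr1 −1.39 ± 0.10). Cell cycle genes fell in 19 of 34 and rose in 2 (20 and 4 adjusted over the list alone, adjusted p = 0.00164), with Cdc20 at −1.03 ± 0.13 and Cdk1 at 0.64 ± 0.10. Oxidative phosphorylation was not called (7 of 30 higher, 1 lower; 5 and 1 adjusted over the list alone, adjusted p = 0.181). With library-size scaling 1 was higher and 13 lower, and the median turned from 0.19 to −0.24. Among called members of that list, Atp5f1a stood at 0.34 ± 0.06 and at −0.09 with library-size scaling.

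Markers of other cells were looked for with fixed lists. In wild-type cells with poly dI:dC against none, the cDC2 list (1 higher, 1 lower of 12; adjusted p = 0.303), the plasmacytoid list (4 higher of 10; adjusted p = 0.44), the monocyte and macrophage list (2 higher, 3 lower of 13; adjusted p = 0.44), the B cell list (2 higher of 4; adjusted p = 0.0815) and the sex-linked genes (2 higher of 4; adjusted p = 0.181) were not called. The summed level of the monocyte and macrophage list was 1510 ± 125 CPM at rest and 464.1 ± 22.2 CPM with poly dI:dC, with Lyz2 at −1.97 ± 0.09 and Ccr2 at −1.86 ± 0.15. Its median log2 fold change was 0.51 and its mean 0.10, and the direction of its test was down. The B cell list rose from 140.9 ± 3.12 to 247.9 ± 7.26 CPM in sum, mostly Ighm. Against these, the cDC1 identity list summed to 8766 ± 354 and 7643 ± 44.6 CPM, the cDC2 list to 142.5 ± 5.2 and 188 ± 13.3 CPM and the plasmacytoid list to 94.45 ± 3.52 and 130.2 ± 8.48 CPM. Of the neutrophil list 0 genes passed the filter on low counts, and of the T and NK cell, mast cell and basophil, erythroid and stromal lists 2 each, so these lists were not tested. Of all 528 list tests, 79 had a median, mean and test that differed in sign, 1 of them called.

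**Figure D3:**
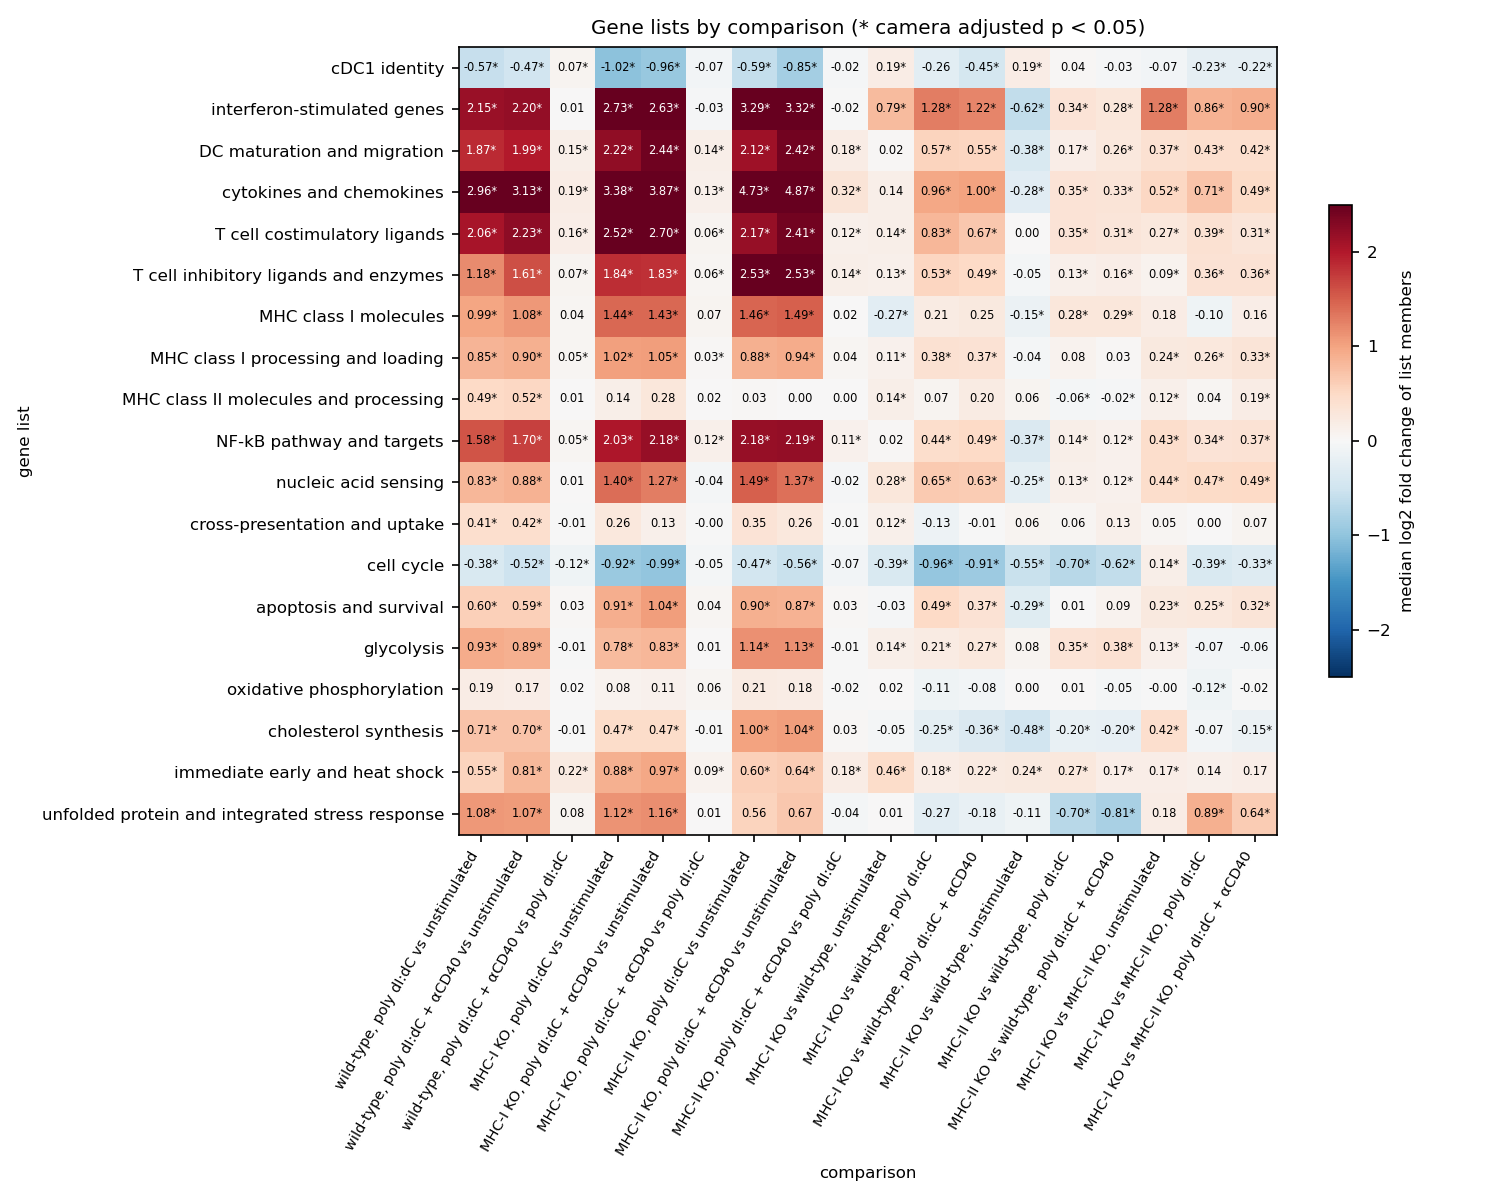
Median log2 fold change of each fixed gene list in the comparisons, on the TMM scale. Interferon-stimulated genes have a median of 2.15 in wild-type, 2.73 in MHC-I KO and 3.29 in MHC-II KO cells with poly dI:dC against unstimulated cells, and medians of stimulated against unstimulated cells are lower with library-size scaling.

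Poly dI:dC plus αCD40 against no stimulation in wild-type cells asks what the full activation mix does. Sp6, a transcription factor gene with 3 counts over the unstimulated libraries, rose 308-fold (exact 95% interval 105 to 1500), Ccl4 246-fold, Dll4 70.8-fold, Ccl3 53.3-fold and Il6, an inflammatory cytokine gene, 45.4-fold. Cxcr3 fell 94.6-fold, Sgsh 59.9-fold, Abhd15 36.4-fold, Slc43a2 29.8-fold, Acss1 29.1-fold and Ccpg1 21.4-fold. All 40 interferon-stimulated genes (median 2.20, adjusted p = 9.41e-36) and all 27 NF-κB genes rose, with 40 and 27 adjusted over the list alone. Cytokines and chemokines rose in 23 of 29 and fell in 1 (23 and 1 adjusted over the list alone, adjusted p = 9.47e-13), Il12b by 3.72 ± 0.06. The stress response list rose in 18 of 19 (18 adjusted over the list alone, adjusted p = 6.04e-10). The cDC1 identity list fell in 14 of 22 and rose in 5 (14 and 5 adjusted over the list alone, adjusted p = 0.000257). Cell cycle genes fell in 20 of 34 and rose in 2 (21 and 3 adjusted over the list alone, adjusted p = 9.43e-05). In all, 5714 genes were called (edgeR), 3024 higher and 2690 lower. Of the lists called, class II genes (adjusted p = 0.00839) had adjusted p = 0.15 with an estimated correlation, and cross-presentation (adjusted p = 0.0139; median 0.42, −0.03 with library-size scaling) had adjusted p = 0.0535 with an estimated correlation.

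Adding αCD40 to poly dI:dC in wild-type cells tests what CD40 engagement adds. Ptgs2, the inducible cyclooxygenase gene, rose by 1.12 ± 0.20 (edgeR adjusted p = 0.0089), Tnf by 0.92 ± 0.11 (4.1e-05) and the Notch ligand gene Jag1 by 0.69 ± 0.12. Ccl3 rose by 0.59 ± 0.09, Tnfsf9 by 0.57 ± 0.10 and Ppp1r15a by 0.57 ± 0.08. Il12b rose by 0.51 ± 0.05 (4.1e-06) and the NF-κB feedback inhibitor genes Nfkbia and Tnfaip3 by 0.50 ± 0.06 and 0.52 ± 0.07. In all, 16 genes were called, all higher. By list, cytokines and chemokines (3 called, 5 adjusted over the list alone, adjusted p = 2.94e-16), maturation genes (0 called, 4 adjusted over the list alone, 5.13e-17), NF-κB genes (2 called, 5 adjusted over the list alone, 9.58e-13), costimulatory ligands (1 called, 3 adjusted over the list alone, 1.29e-07) and immediate early genes (1 called, 4 adjusted over the list alone, 1.4e-13) rose as sets. The cell cycle list fell (median −0.12, adjusted p = 0.00016). Inhibitory ligands (adjusted p = 0.00139), cDC1 identity (0.0411) and class I processing (0.0481) had adjusted p = 0.0806, 0.0595 and 0.222 with an estimated correlation, and the cDC1 list had a median of 0.07 and a mean of −0.03. Interferon-stimulated genes were not called (adjusted p = 0.359). Leaving out replicate 2 or 3 of the poly dI:dC group left 8 genes called and leaving out replicate 3 of the αCD40 group 10, while DESeq2 called 42.

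The same comparisons in MHC-I KO cells show their response. With poly dI:dC, Sp6 rose from 0 counts (at least 282-fold), and Ccl4 rose 177-fold, Il6 160-fold, Dll4 146-fold and the lymphotoxin gene Lta 144-fold. Abhd15 (at least 217-fold) and Sgsh (at least 191-fold) fell to 0 counts, Kif5a to 3 counts (196-fold, exact 95% interval 67 to 954), and Mfng, a Notch-modifying enzyme gene, fell 118-fold, Lpar5 103-fold and Slc43a2 68.1-fold. All 40 interferon-stimulated genes rose (40 adjusted over the list alone, median 2.73, adjusted p = 3.51e-35; Gbp5 5.32 ± 0.12). So did 25 of 27 maturation genes (25 adjusted over the list alone, 1.4e-23; Ccr7, the lymph node homing receptor gene, 2.83 ± 0.07) and all 27 NF-κB genes (27 adjusted over the list alone, 1.31e-26; Cflar 3.19 ± 0.08). Cytokines rose in 21 of 29 and fell in 1 (21 and 1 adjusted over the list alone, 1.46e-09; Il12b 4.36 ± 0.06). Cell cycle genes fell in 26 of 34 and rose in 3 (26 and 4 adjusted over the list alone, 1.99e-06; Cdc20 −2.27 ± 0.14). Genes of the cDC1 identity list fell in 15 of 22 and rose in 3 (16 and 3 adjusted over the list alone, 1.44e-05; Itgae −3.06 ± 0.10). Cholesterol synthesis rose in 12 of 20 and fell in 3 (12 and 3 adjusted over the list alone, 0.00107), and its median of 0.47 turned to −0.17 with library-size scaling. In all, 7581 genes were called (edgeR), 3585 higher and 3996 lower. Immediate early genes (adjusted p = 0.0274) had adjusted p = 0.219 with an estimated correlation. The monocyte and macrophage list summed to 1460 ± 122 CPM at rest and 404.7 ± 16.1 CPM with poly dI:dC, with Ccr2 at −3.77 ± 0.17.

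With αCD40 added, 7478 genes differed from unstimulated MHC-I KO cells, 3586 higher and 3892 lower. Sp6 was at least 340-fold higher, Rhbdl3 698-fold (exact 95% interval 125 to 27600) and Il6 234-fold, while Abhd15 fell 117-fold, Mfng 106-fold, Sigirr, a brake on IL-1 receptor signalling, 76.2-fold and Cxcr3 51.4-fold. All 40 interferon-stimulated genes and 26 of 27 maturation genes rose, with 40 and 26 adjusted over the list alone (adjusted p = 3.73e-35 and 2.72e-25). Immediate early genes (adjusted p = 0.00395) had adjusted p = 0.109 with an estimated correlation, and cholesterol synthesis had a median of 0.47, and of −0.20 with library-size scaling. Against poly dI:dC alone, αCD40 raised 32 genes and lowered 3 (edgeR; 91.4% higher, and 83.3% with library-size scaling). Ptgs2 rose by 0.96 ± 0.21 (adjusted p = 0.032), Fam98a by 0.94 ± 0.21, Tnf by 0.88 ± 0.11, Dgkz by 0.86 ± 0.18, Tnfsf9 by 0.74 ± 0.10 and Jag1 by 0.72 ± 0.12, and the PI3 kinase gene Pik3cg fell by 0.43. NF-κB genes rose as a set (4 called, 7 adjusted over the list alone, adjusted p = 1.45e-18; Nfkbia 0.70 ± 0.06), and so did cytokines (2 called, 4 higher and 1 lower adjusted over the list alone, 1.19e-06). Inhibitory ligands (adjusted p = 0.0215) and class I processing (0.0471) both had adjusted p = 0.219 with an estimated correlation. Without replicate 1 or 2 of the poly dI:dC group 11 and 23 genes were called, and without replicate 2 of the αCD40 group 15. A fit of these groups alone called 8, DESeq2 60.

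In MHC-II KO cells poly dI:dC raised Ccl4 337-fold, Ccl3 by 6.95 ± 0.14, Dll4 by 6.76 ± 0.58, Tnfsf15 by 6.32 ± 0.32 and Cxcl10 by 6.28 ± 0.18. Acss1 fell most (−7.06 ± 0.58), followed by the kinase gene Map2k6 (−6.09 ± 0.87), Card10 (−5.86 ± 0.51) and Tmt1a (−5.78 ± 0.79). Interferon-stimulated genes rose in 40 of 40 (40 adjusted over the list alone, median 3.29, adjusted p = 6.05e-35; Rsad2 5.95 ± 0.12), as did all 27 NF-κB genes (27 adjusted over the list alone, 7.7e-29) and 25 of 27 maturation genes (25 adjusted over the list alone, 3.62e-23; Cd40 4.15 ± 0.09). Cytokines rose in 23 of 29 and fell in 1 (24 and 1 adjusted over the list alone, 2e-09; Il12b 4.18 ± 0.06). The stress response list was not called (9 of 19 higher, 4 lower; 11 and 4 adjusted over the list alone, 0.0616). Hspa5 rose by 0.73 ± 0.05 and Edem1, a factor of protein degradation, by 1.11 ± 0.07, while the protein disulfide isomerase gene Pdia4 fell by 1.28 and the transcription factor gene Xbp1 by 0.52. Cell cycle genes fell in 19 of 34 and rose in 4 (21 and 4 adjusted over the list alone, 0.00176), and cDC1 identity genes fell in 16 of 22 and rose in 4 (16 and 4 adjusted over the list alone, 3.16e-05). In all, 6985 genes were called (edgeR), 3547 higher and 3438 lower. Immediate early genes (adjusted p = 0.0295) had adjusted p = 0.195 with an estimated correlation. The monocyte and macrophage list summed to 1845 ± 67 CPM at rest and 600.4 ± 47.3 CPM with poly dI:dC.

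With αCD40 added, 7196 genes differed from unstimulated MHC-II KO cells (edgeR), 3579 higher and 3617 lower, with Ccl4 at 8.70, Ccl3 at 7.64 ± 0.14, Dll4 at 7.58 ± 0.57 and Lta at 7.56 ± 0.70. Interferon-stimulated genes rose in 40 of 40 (40 adjusted over the list alone, adjusted p = 1.14e-33), and the stress response list was not called (9 higher, 4 lower; 10 and 5 adjusted over the list alone, 0.137, with 6 higher and 9 lower under library-size scaling). Immediate early genes (adjusted p = 0.00569) had adjusted p = 0.128 with an estimated correlation. Against poly dI:dC alone αCD40 raised 26 genes and lowered 5. Ptgs2 rose by 1.53 ± 0.21 (adjusted p = 0.00011), Tnf by 0.85 ± 0.11, Il12b by 0.62 ± 0.05 and Tnfaip3 by 0.69 ± 0.07. Tifab fell by 0.54, Txnip, an inhibitor of thioredoxin, by 0.50 and Stard4, a cholesterol carrier gene, by 0.48. NF-κB genes (3 called, 7 adjusted over the list alone, adjusted p = 2.12e-15) and cytokines (3 called, 6 adjusted over the list alone, 4.3e-13) rose as sets, and inhibitory ligands (0.00924) had adjusted p = 0.206 with an estimated correlation. Leaving out replicate 1 or 2 of the poly dI:dC group gave 19 and 15 genes, leaving out any 1 library of the αCD40 group 19 to 20, and DESeq2 called 98.

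Unstimulated MHC-I KO against unstimulated wild-type cells asks what loss of classical class I does at rest. Interferon-stimulated genes stood out: 34 of 40 were higher and none lower (35 and 0 adjusted over the list alone, median 0.79, adjusted p = 3.82e-55, and 2.8e-05 with an estimated correlation). Ifit3, an antiviral gene, was higher by 2.00 ± 0.18, Cmpk2 by 1.90 ± 0.12, Rsad2 by 1.65 ± 0.11 and Oasl1 by 1.05 ± 0.06. H2-T24, a non-classical class I gene, was higher by 1.95 ± 0.16 and the early response gene Egr2 by 1.77 ± 0.24. Plet1, a surface protein gene, was lower by a log2 fold change of −2.14 ± 0.19, Spns3 by −1.51 ± 0.29, Ears2 by −1.41 ± 0.31 and the sorting receptor gene Sort1 by −1.37 ± 0.37. In all, 572 genes were called (edgeR), 395 higher and 177 lower, and the share of higher genes went from 69.1% to 46.5% with library-size scaling.

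Nucleic acid sensors were also higher here, in 12 of 24 with none lower (14 and 0 adjusted over the list alone, adjusted p = 1.19e-15; Ifi204 1.22 ± 0.09, Zbp1 0.84 ± 0.09). Immediate early genes were higher in 12 of 23 with 1 lower (18 and 1 adjusted over the list alone, 8e-24; Egr1 0.98 ± 0.10, Atf3 0.79 ± 0.07, Ier3 −0.58 ± 0.16). Cell cycle genes were lower in 8 of 34 with none higher (19 and 0 adjusted over the list alone, 6.02e-18; Cdc20 −0.71 ± 0.13, Ube2c −0.66 ± 0.12). The cDC1 identity list was higher in 6 of 22 and lower in 1 (9 and 1 adjusted over the list alone, 7.06e-08; Irf8, the transcription factor that sets cDC1 fate, 0.47 ± 0.05), and glycolysis in 5 of 20 (9.75e-06; Hk3 1.13 ± 0.13). Costimulatory ligands were higher in 6 of 15 (6 higher and 1 lower adjusted over the list alone, 0.00282; Tnfsf9 0.96 ± 0.13), and class I processing genes in 3 of 18 (6 adjusted over the list alone, 0.000146; Tapbp 0.32 ± 0.06). Class II genes were higher in 4 of 21 (4 adjusted over the list alone, 8.67e-06; H2-Ob 0.46 ± 0.07) and cross-presentation genes in 3 of 20 (6 higher and 1 lower adjusted over the list alone, 0.00291; Axl 0.98 ± 0.05). The call of the class I list (2 higher, 6 lower of 14; 4 and 7 adjusted over the list alone, 0.000447; median −0.27, also with H2-D1 at its bound) rested on the deleted genes. Without H2-K1 and H2-D1 2 were higher and 4 lower of 12 (adjusted p = 0.72; median −0.20, mean 0.009). Inhibitory ligands (2 higher; 0.0149) had adjusted p = 0.166 with an estimated correlation. Cytokines were not called as a set (4 higher, 4 lower of 29; 10 and 6 adjusted over the list alone, 0.922): Cxcl10 was higher by 1.46 ± 0.17 and Cxcl9 by 1.07 ± 0.13, and Il1b was lower at −1.33 ± 0.14. Maturation (0.964) and NF-κB genes (0.964) were not called, nor was the monocyte and macrophage list (1 higher of 13; 0.436), in which Cd68 was higher by 0.68 ± 0.12. Ighm of the B cell list was higher by 0.56 ± 0.08.

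MHC-I KO differed from wild-type cells with poly dI:dC in 3952 genes (edgeR), 1911 higher and 2041 lower. The comparison asks whether activated cells without class I reach the same state. All 40 interferon-stimulated genes were higher (40 adjusted over the list alone, median 1.28, adjusted p = 2.13e-57). Also higher were Slfn4 (2.83 ± 0.40), Plagl1 (2.59 ± 0.51), the cytokine subunit gene Il27 (2.48 ± 0.55), the DNA sensor family gene Ifi208 (2.35 ± 0.61) and Lta (2.16 ± 0.45). Plet1 was lower (−2.90 ± 0.21), as were Plxdc2 (−2.78 ± 0.30), the mitosis gene Cdca3 (−2.59 ± 0.18) and Tnfaip8l1 (−2.56 ± 0.45). Maturation genes were higher in 22 of 27 and lower in 1 (22 and 1 adjusted over the list alone, 1.67e-19; Ccr7 0.97 ± 0.07, Ccl5 1.29 ± 0.10, Tbc1d4 −0.27 ± 0.06). NF-κB genes were higher in 21 of 27 and lower in 1 (22 and 2 adjusted over the list alone, 6.29e-15; Cflar 1.12 ± 0.08, Irf1 0.77 ± 0.06). Cytokines were higher in 16 of 29 and lower in 4 (16 and 5 adjusted over the list alone, 2.49e-06), with Il12b at 1.29 ± 0.06, Tnf at 1.31 ± 0.12 and Il1b at −1.23 ± 0.14. Costimulatory ligands were higher in 9 of 15 and lower in 1 (2.04e-07; Cd40 0.95 ± 0.08, Cd48 −0.80 ± 0.16) and inhibitory ligands in 11 of 17 (3.36e-08; Cd200 1.15 ± 0.09, Cd274 0.66 ± 0.06). Cell cycle genes were lower in 26 of 34 and higher in 1 (27 and 1 adjusted over the list alone, 7.37e-17; Cdc20 −1.94 ± 0.14, Bub1b −1.70 ± 0.12, Tpx2 0.36 ± 0.10). Cholesterol synthesis genes were lower in 11 of 20 and higher in 1 (14 and 1 adjusted over the list alone, 5.79e-05; Mvd −0.82 ± 0.11).

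The class I list was not called here (4 higher, 3 lower of 14; adjusted p = 0.972; median 0.21 and mean −1.04 with the deleted genes at their values by count, and median −0.07 with library-size scaling), nor without the deleted genes (4 higher, 1 lower of 12; 0.0622). H2-T24 stood at 1.65 ± 0.15 and the β2-microglobulin gene B2m at 0.54 ± 0.08. Neither was the class II list (6 higher, 5 lower of 21; 0.69; median 0.07, mean −0.07, and median −0.21 with library-size scaling) or the cDC1 identity list (4 higher, 9 lower of 22; 10 lower adjusted over the list alone, 0.0697; Irf8 0.73 ± 0.05, Naaa −0.92 ± 0.08). Glycolysis genes were higher in 11 of 20 (0.000109) and immediate early genes in 10 of 23 with 6 lower (0.00339, adjusted p = 0.113 with an estimated correlation), and both medians turned with library-size scaling, to −0.07 and −0.10. That scaling moved the median of all genes by −0.28 and the share of higher genes from 48.4% to 19.3%, and median-of-ratios factors moved that share to 57.3%. The monocyte and macrophage list was not called (0.377), with Ccr2 at −1.85 ± 0.17.

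With αCD40 added, 3542 genes differed between MHC-I KO and wild-type cells (edgeR), 1799 higher and 1743 lower (50.8% higher, 59.1% with median-of-ratios factors, and 18.3% with library-size scaling, which moved the median by −0.29). Interferon-stimulated genes were higher in 40 of 40 (40 adjusted over the list alone, median 1.22, adjusted p = 3.33e-59). So were 21 of 27 maturation genes with none lower (22 and 1 adjusted over the list alone, 9.76e-21; Ccr7 1.02 ± 0.07) and 21 of 27 NF-κB genes with none lower (22 and 1 adjusted over the list alone, 7.97e-20). The connexin gene Gjb2 (2.35 ± 0.47), Plagl1 (2.34 ± 0.50), Slfn4 (2.31 ± 0.39) and Il27 (2.26 ± 0.54) were among the highest. Plet1 (−2.61 ± 0.21), the mitosis genes Kif14 (−2.25 ± 0.27) and Spc25 (−2.13 ± 0.30) and Zfp36l2 (−2.19 ± 0.13) were among the lowest. Cell cycle genes were lower in 25 of 34 and higher in 1 (27 and 1 adjusted over the list alone, 1.54e-15). The cDC1 identity list was lower in 12 of 22 and higher in 3 (12 and 4 adjusted over the list alone, 0.00255; Naaa −1.06 ± 0.08). Cytokines were higher in 13 of 29 and lower in 5 (14 and 7 adjusted over the list alone, 2.11e-05; Il12b 1.12 ± 0.05). Immediate early genes (adjusted p = 0.00416) had adjusted p = 0.124 with an estimated correlation. Medians of the glycolysis, immediate early, class II and class I lists turned with library-size scaling, to −0.02, −0.07, −0.09 and −0.04.

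Unstimulated MHC-II KO against unstimulated wild-type cells asks what loss of class II does at rest. Interferon-stimulated genes were lower in 33 of 40 and higher in none (36 and 0 adjusted over the list alone, median −0.62, adjusted p = 7.82e-23), with Gbp2 at −1.28 ± 0.08, Gbp5 at −1.25 ± 0.12 and Oasl2 at −0.84 ± 0.08. The inflammatory cytokine gene Il1b (−3.45 ± 0.15) and the lipoprotein receptor gene Tlr2 (−2.20 ± 0.29) were lower. Early growth response genes were higher, Egr4 by 3.38 ± 0.71, Egr3 by 2.48 ± 0.19 and Egr2 by 2.09 ± 0.24, as were the lectin gene Cd209a (2.23 ± 0.57) and the signalling adaptor gene Lcp2 (1.92 ± 0.22). Btnl2, a butyrophilin-like gene beside the class II cluster, stood at 194 CPM against 0.3 CPM in wild-type cells. In all, 1205 genes were called (edgeR), 421 higher and 784 lower, with a higher mitochondrial share (1.48% against 0.972%).

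NF-κB genes were lower in 21 of 27 and higher in none (21 adjusted over the list alone, adjusted p = 2.63e-17; Bcl3 −1.28 ± 0.12, Traf1 −0.81 ± 0.06, Relb −0.63 ± 0.07). Maturation genes were lower in 16 of 27 and higher in 2 (17 and 2 adjusted over the list alone, 6.06e-08; Marcksl1 −0.63 ± 0.07, Fscn1 0.47 ± 0.10). Cholesterol synthesis was lower in 14 of 20 (17 adjusted over the list alone, 9.42e-15; Hmgcs1 −0.74 ± 0.06), and cell cycle in 19 of 34 (24 adjusted over the list alone, 1.44e-20; Ube2c −0.90 ± 0.12). Apoptosis and survival genes were lower in 10 of 26 (11 adjusted over the list alone, 1.01e-06; Bcl2a1a −1.10 ± 0.12) and nucleic acid sensing in 11 of 24 with 2 higher (13 and 2 adjusted over the list alone, 1.8e-05; Zbp1 −1.22 ± 0.10, Tlr3 0.79 ± 0.14). Immediate early genes were higher in 10 of 23 and lower in 2 (11 and 7 adjusted over the list alone, 1.62e-06; Egr1 1.25 ± 0.10, Ier3 −1.12 ± 0.16). Genes of the cDC1 identity list were higher in 7 of 22 and lower in 2 (8 and 2 adjusted over the list alone, 2.25e-06; Cadm1 0.77 ± 0.07, Itgae 0.71 ± 0.09). Cytokines were lower in 8 of 29 and higher in 1 (10 and 2 adjusted over the list alone, 0.0125, adjusted p = 0.197 with an estimated correlation; Ccl3 −1.85 ± 0.16, Il12b −0.58 ± 0.06). The class I list was lower (2 higher, 4 lower of 14; 2 and 5 adjusted over the list alone, 0.0107). The class II list was not called (5 higher, 4 lower of 21; 0.863; median 0.06 and mean −2.43 with H2-Aa, H2-Eb1 and H2-Eb2 at their bounds), the 4 lower genes being the deleted ones. Without them 5 of 17 were higher and none lower (0.00265, adjusted p = 0.0863 with an estimated correlation). The monocyte and macrophage list was higher (2 higher, 1 lower of 13; 3 and 1 adjusted over the list alone, 0.0119, adjusted p = 0.0816 with an estimated correlation), with a summed level of 1845 ± 67 against 1510 ± 125 CPM, Cd68 at 0.61 ± 0.11 and Lyz2 at 0.29 ± 0.09. The cDC2 list was not called (2 higher of 12; 0.134), with Itgam at 1.07 ± 0.16.

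MHC-II KO differed from wild-type cells with poly dI:dC in 1438 genes (edgeR), 723 higher and 715 lower (50.3% higher, 27.8% with library-size scaling and 61% with median-of-ratios factors). The comparison asks whether activated cells without class II reach the same state. Unfolded protein and integrated stress response genes were lower in 10 of 19 and higher in 1 (11 and 1 adjusted over the list alone, median −0.70, adjusted p = 2.08e-17). Creld2, a chaperone of the endoplasmic reticulum, stood at −2.41 ± 0.14, Pdia4 at −2.29 ± 0.17, Hsp90b1 at −1.31 ± 0.06 and Hspa5 at −0.87 ± 0.05, with Sesn2 at 0.55 ± 0.14. Derl3, a component of endoplasmic reticulum protein degradation, was lowest among the named genes outside the deletion (−5.53 ± 0.79), with Slc8a2 (−2.46 ± 0.37). Higher genes were Btnl2 (292 CPM), the thrombin receptor gene F2r (2.29 ± 0.46), Ermardl2 (2.00 ± 0.23), Gpr31b (1.81 ± 0.29), the neutrophil chemokine gene Cxcl3 (1.72 ± 0.53) and the potassium channel gene Kcnn4 (1.65 ± 0.21). Interferon-stimulated genes were higher in 21 of 40 and lower in none (24 and 0 adjusted over the list alone, 1.06e-21; Oasl1 0.75 ± 0.06). Glycolysis genes were higher in 15 of 20 and lower in none (15 adjusted over the list alone, 5.5e-15; the glucose transporter gene Slc2a1 0.79 ± 0.11), and cell cycle genes were lower in 23 of 34 and higher in none (27 adjusted over the list alone, 4.44e-23; Cdc20 −1.12 ± 0.14). Without replicate 3 of the MHC-II KO group, 17 interferon-stimulated and 11 glycolysis genes were higher and 10 stress response and 22 cell cycle genes lower.

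Costimulatory ligands were higher in 6 of 15 in this comparison (8 adjusted over the list alone, adjusted p = 3.21e-05, and 0.0802 for the 11 members in no other list; Cd86 0.45 ± 0.07). Class I molecules were higher in 6 of 14 and lower in 2 (8 and 3 adjusted over the list alone, 0.000233; H2-K1 0.31 ± 0.07, H2-D1 0.33 ± 0.07) and NF-κB genes in 5 of 27 and lower in 1 (10 and 2 adjusted over the list alone, 4.11e-05; Tnfaip3 0.59 ± 0.07). Class I processing genes were not called as a set (3 higher, 4 lower of 18; 0.824): Pdia6 (−1.02 ± 0.07) and Calr (−0.64 ± 0.07), chaperones of the endoplasmic reticulum, were lower and Tapbp was higher (0.37 ± 0.06). Lists called here with adjusted p = 0.175, 0.181, 0.181, 0.0501 and 0.131 with an estimated correlation were cytokines (0.00991; Il12b 0.40 ± 0.05, Il1b −1.57 ± 0.14), inhibitory ligands (0.023), class II genes (0.00991), immediate early genes (0.000206) and cDC2 markers (0.0453, 2 lower of 12). The class II call rested on the deleted genes, and without them 2 were higher and 3 lower of 17 (adjusted p = 0.565). With αCD40 added, 1378 genes differed (edgeR), 736 higher and 642 lower (53.4% higher, 28.5% with library-size scaling and 63.5% with median-of-ratios factors). The stress response list was lower in 10 of 19 and higher in 1 (14 and 1 adjusted over the list alone, median −0.81, adjusted p = 4.42e-20; Pdia4 −3.05 ± 0.18, Creld2 −2.55 ± 0.14). Glycolysis genes were higher in 14 of 20 (17 adjusted over the list alone, 7.16e-16), interferon-stimulated genes higher in 18 of 40 (22 adjusted over the list alone, 1.98e-17) and cell cycle genes lower in 20 of 34 (23 adjusted over the list alone, 1.59e-20). Derl3 (−5.63 ± 0.80) was lowest among the named genes outside the deletion and Gpr31b (2.13 ± 0.29), F2r (1.95 ± 0.45) and the collagen gene Col4a2 (1.78 ± 0.54) among the highest. Cytokines (0.00164), inhibitory ligands (0.017) and class II genes (0.00476; median −0.02, and 0.02 with median-of-ratios factors) had adjusted p = 0.101, 0.165 and 0.165 with an estimated correlation. Without the deleted genes the class II list had 2 higher and 2 lower of 17 (adjusted p = 0.752).

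**Figure D4:**
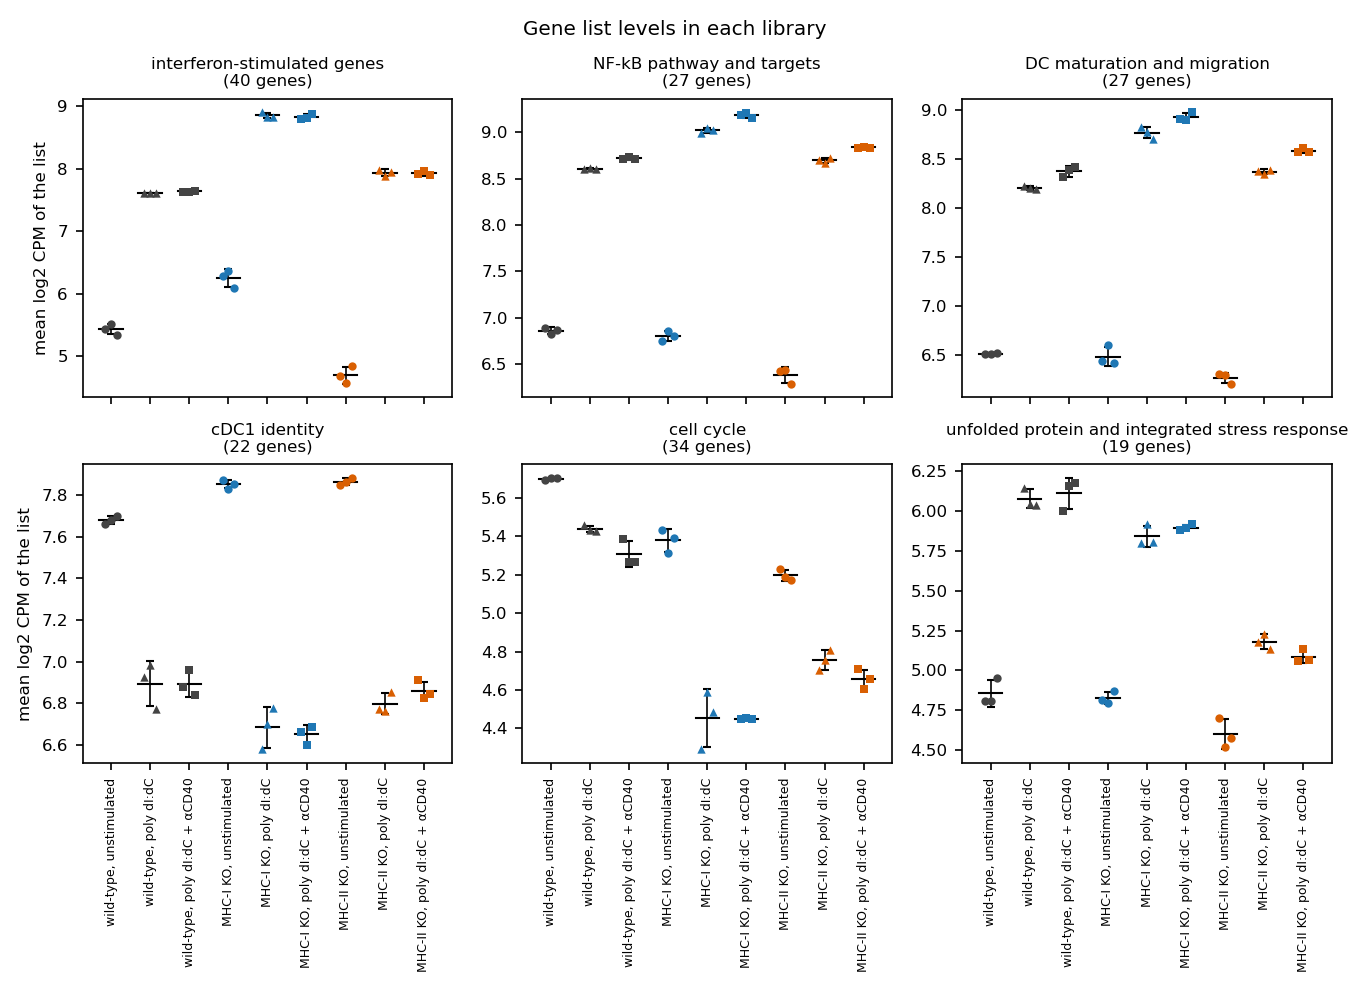
Mean log2 CPM of gene lists is shown for each library by genotype and treatment. Interferon-stimulated genes average 5.43 in unstimulated wild-type, 6.24 in MHC-I KO and 4.69 in MHC-II KO libraries, and the stress response list averages 6.08 in wild-type and 5.18 in MHC-II KO libraries with poly dI:dC.

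MHC-I KO against MHC-II KO cells compares the knockouts directly. Interferon-stimulated genes were higher in the MHC-I KO in 39, 39 and 40 of 40 at rest, with poly dI:dC and with αCD40 added (40 each adjusted over the list alone, medians 1.28, 0.86 and 0.90; adjusted p = 2.38e-74, 1.36e-60 and 1.34e-69). At rest Ifit3b (4.03 ± 0.38) and Ifi213 (2.92 ± 0.24) were higher and the transcription factor gene Tcf7 (−2.62 ± 0.40), Lcp2 (−1.71 ± 0.22) and Ermardl2 (−1.67 ± 0.23) lower. At rest cholesterol synthesis was higher in 11 of 20 (16 adjusted over the list alone, 7.81e-12; Hmgcs1 0.84 ± 0.06). With poly dI:dC Plac8 (2.69 ± 0.64) and Rnaset2b (2.21 ± 0.14) were higher and Dcstamp, a cell fusion gene of osteoclasts, (−3.33 ± 0.33), Kcnn4 (−2.42 ± 0.22) and Polr1h (−2.09 ± 0.16) lower. With αCD40 added Derl3 (5.65 ± 0.80) and Pdia4 (2.46 ± 0.18) were higher and the platelet chemokine gene Ppbp (−3.55 ± 0.57) and Cxcl3 (−2.54 ± 0.55) lower. Stress response genes were higher in 10 of 19 and lower in 2 with poly dI:dC (10 and 3 adjusted over the list alone, 1.04e-07) and with αCD40 (11 and 2 adjusted over the list alone, 4.82e-10). Cell cycle genes were lower in 15 and 13 of 34 with 2 higher (17 and 16 lower adjusted over the list alone, 7.55e-05 and 0.000886). The counts of called genes (edgeR) were 1114 at rest (839 higher), 2631 with poly dI:dC (1420 higher) and 2195 with αCD40 (1236 higher), and the shares of higher genes went from 75.3%, 54% and 56.3% to 53.7%, 23.9% and 21.7% with library-size scaling. A fit of these groups alone called 694 at rest.

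Lists of that comparison whose calls were lost with an estimated correlation were, at rest, cytokines (adjusted p = 0.00451, and 0.148 with an estimated correlation), inhibitory ligands (0.0196 and 0.172; median −0.01 with library-size scaling), class II genes (0.00451 and 0.172), cell cycle (0.00451 and 0.0998), glycolysis (0.0318 and 0.261), immediate early genes (0.0303 and 0.241) and cDC2 markers (0.0275 and 0.0998, 2 lower of 12). With poly dI:dC this was oxidative phosphorylation (0.0323 and 0.481), and with αCD40 class II genes (0.0217 and 0.277; median −0.01 with library-size scaling) and cholesterol synthesis (0.00795 and 0.0899). Without the deleted genes the class II list was not called at rest or with αCD40 (adjusted p = 0.962 and 0.665).

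The interaction contrasts test whether a knockout's response to poly dI:dC differs from the wild-type response. In the MHC-I KO the response was larger for maturation genes (18 of 27 with a positive interaction and none negative; 20 adjusted over the list alone, adjusted p = 6.56e-20; Ccr7 0.88 ± 0.09, Traf1 0.78 ± 0.08). So it was for NF-κB genes (19 of 27, none negative; 23 adjusted over the list alone, 1.56e-16; Cflar 0.79 ± 0.11) and interferon-stimulated genes (14 of 40, none negative; 17 adjusted over the list alone, 4.27e-11; Gbp5 1.65 ± 0.15). The maturation and NF-κB lists share 4 genes, Traf1 among them, and without all genes of more than 1 list had adjusted p = 9.94e-14 and 1.38e-09. It was more negative for cell cycle genes (21 of 34 negative, 1 positive; 23 and 1 adjusted over the list alone, 8.49e-12; Bub1b −1.12 ± 0.17, Tpx2 0.86 ± 0.14), for cDC1 identity (10 of 22 negative, 2 positive; 12 and 4 adjusted over the list alone, 3.31e-05; Naaa −1.22 ± 0.11, Itgae −1.15 ± 0.13) and cholesterol synthesis (7 of 20; 8 adjusted over the list alone, 0.000474). Single cytokine genes differed, Il6 by 2.46 ± 0.33, Tnf by 1.48 ± 0.19 and Il12b by 1.15 ± 0.08. The cytokine list (adjusted p = 0.0144) had adjusted p = 0.215 with an estimated correlation and class I processing (0.0117) 0.0927 with an estimated correlation. Cytokine and nucleic acid sensing medians turned with library-size scaling, to −0.10 and −0.01. In all, 1852 genes were called (edgeR), 908 positive and 944 negative, and positive genes made up 49%, 18.8% with library-size scaling and 58.7% with median-of-ratios factors.

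In the MHC-II KO the response to poly dI:dC was larger than in wild-type cells for interferon-stimulated genes (36 of 40 positive, none negative; 39 adjusted over the list alone, median 0.98, adjusted p = 2.41e-50; Rsad2 1.67 ± 0.15, Gbp2 1.39 ± 0.11). So it was for NF-κB genes (19 of 27, none negative; 23 adjusted over the list alone, 1.88e-29; Tnfaip3 0.90 ± 0.10) and maturation genes (17 of 27, none negative; 17 and 1 adjusted over the list alone, 4.3e-18; Cd40 1.07 ± 0.11), which without genes of more than 1 list had adjusted p = 7.11e-17 and 2.75e-08. It was smaller for the stress response (9 of 19 negative, none positive; 9 and 2 adjusted over the list alone, 1.88e-11; Pdia4 −2.18 ± 0.23, Creld2 −1.77 ± 0.19, Hsp90b1 −1.03 ± 0.08). It was more negative for cDC1 identity genes (6 of 22; 7 adjusted over the list alone, 0.000205; Tlr11 −1.46 ± 0.30, Flt3 −0.47 ± 0.08). Cytokines were positive in 8 of 29 (11 and 1 adjusted over the list alone, 0.000142; Cxcl9 2.18 ± 0.19), class I molecules in 6 of 14 (9 adjusted over the list alone, 1.94e-08) and glycolysis genes in 7 of 20 (11 adjusted over the list alone, 9.55e-07). Inhibitory ligands (adjusted p = 0.0427) and cell cycle (0.0192) had adjusted p = 0.237 and 0.139 with an estimated correlation. The larger responses of the interferon, NF-κB and maturation lists lay partly in lower levels at rest. Interferon-stimulated genes averaged 4.691 log2 CPM in MHC-II KO and 5.429 in wild-type libraries at rest, and 7.94 and 7.613 with poly dI:dC. NF-κB genes averaged 6.381 and 6.86 at rest, and 8.695 and 8.606 with poly dI:dC. Maturation genes averaged 6.266 and 6.51, and then 8.373 and 8.207. In all, 887 genes were called (edgeR), 592 positive and 295 negative, and positive genes made up 66.7%, and 43.3% with library-size scaling. Without replicate 3 of the MHC-II KO group with poly dI:dC, 34 interferon-stimulated genes were positive and 8 stress response genes negative.

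For the effect of adding αCD40, edgeR called 0 genes as different between MHC-I KO and wild-type cells, with 663 at an unadjusted p under 0.05, and DESeq2 called 1. Between MHC-II KO and wild-type cells edgeR called 0, with 635 at an unadjusted p under 0.05, and DESeq2 called 12. No list member was called in either contrast. In the first, the cytokine list was called as lower with no member called and had adjusted p = 0.446 with an estimated correlation, and in the second no list was called. Counts without 1 library reached 1 without replicate 3 of wild-type with poly dI:dC and 6 without replicate 2 of the MHC-I KO with poly dI:dC in the first, and 1 without replicate 3 of the MHC-II KO with poly dI:dC in the second.

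Called differences of both knockouts from wild-type cells were counted together to ask how far the knockouts share them. At rest 219 genes were called in the same direction in both (106 higher, 113 lower) and 104 in opposite directions, with poly dI:dC 1036 (541 higher, 495 lower) and 62, and with αCD40 added 1012 (572 higher, 440 lower) and 35. Independent lists of these sizes would share 21.2, 198 and 170. Simulated unchanged groups, compared with simulated wild-type libraries in common, shared 0.05, 0 and 0 on average over 20 simulations. Groups without any change yield few calls, so these simulated counts are no benchmark for the real ones. The log2 fold changes of the knockouts correlated across genes, which are not independent replicates, at r = 0.395, 0.493 and 0.517 (Spearman 0.353, 0.498 and 0.533), against 0.501, 0.499 and 0.495 in the simulations. The covariance was 0.527, 0.833 and 0.846 against a simulated 0.454, 0.473 and 0.467, a difference of 0.0731, 0.36 and 0.379. The 3 wild-type libraries of a treatment cannot be split into groups of at least 2 each, so part of the excess may come from the shared controls.

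Genes near the H2 locus were tested because both knockouts carry strain names of embryonic stem cells from outside C57BL/6J, so linked genes can differ by strain of origin. Within 10 Mb of the span from H2-K1 to H2-D1, 28 of 355 tested genes (7.89%) were called between unstimulated MHC-I KO and wild-type cells against 3.95% elsewhere (odds ratio 2.08, Fisher's exact adjusted p = 0.00386). With poly dI:dC and with αCD40 added the odds ratios were 1.14 and 1.04 (exact adjusted p = 0.329 and 0.757). For the MHC-II KO the odds ratio was 1.5 at rest (43 genes, exact adjusted p = 0.0453), 1.86 with poly dI:dC (61 genes, exact adjusted p = 0.00049) and 1.64 with αCD40 added (53 genes, exact adjusted p = 0.00588). Without the targeted genes the odds ratios at rest were 1.96 for the MHC-I KO (unadjusted exact p = 0.00332) and 1.37 for the MHC-II KO (0.079), which had 1.68 with poly dI:dC (0.00115) and 1.46 with αCD40 (0.022). Between the knockouts the odds ratio was 1.47 at rest (exact adjusted p = 0.0624). With a window of 20 Mb or all of chromosome 17, the calls for both knockouts at rest and for the MHC-II KO with αCD40 were lost.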

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

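The splits of the libraries, the tests of scaling and of single libraries, and the look for culture labels were chosen only after the results were seen, and the tests of GC content and transcript length before. The response to poly dI:dC differed between genotypes by the interaction test of edgeR in 1852 genes for the MHC-I KO and 887 genes for the MHC-II KO, each against wild-type cells.

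For the MHC-I KO positive interactions with large log2 differences of responses were the complement gene Hc (2.76 ± 0.51), Il6 (2.46 ± 0.33), B3gnt2 (2.35) and Fgfbp3 (2.25 ± 0.26). The negative ones were Mfng (−3.70 ± 0.96), Kif5a (−3.40 ± 0.82), Mns1 (−3.35 ± 0.73), Nudt8 (−3.20 ± 0.91) and the cyclooxygenase gene Ptgs1 (−3.07 ± 0.75). For the MHC-II KO they were H2-Eb1 (5.76), H2-Aa (5.76), the cytokine signalling gene Cish (3.67 ± 1.07) and Ifit3b (2.70 ± 0.51), and Dhrs7 (−2.99 ± 0.90), Card10 (−2.86 ± 0.65), Lyl1 (−2.19 ± 0.64), Pdia4 (−2.18 ± 0.23) and Cd200r1 (−2.13 ± 0.50). H2-Eb1 and H2-Aa were at 0 counts in unstimulated knockout cells, so their fitted differences depend on the prior count and are no bounds. Both rested on replicate 3 of the MHC-II KO with poly dI:dC and stood at −0.62 and −0.51 without it.

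Interferon-stimulated genes averaged 0.81 higher on the log2 scale in unstimulated MHC-I KO than in wild-type libraries (pooled SD 0.117) and −0.74 in MHC-II KO libraries (pooled SD 0.113). With library-size scaling alone the differences were 0.74 and −0.72, but TMM factors at rest were too alike to test scaling. A trend with GC content or transcript length is argued against by 0.80 and −0.69 after its removal. A difference between cultures or sort days stays open: 0 of 27 libraries have a label for either, so culture and genotype cannot be told apart. Effects of strain of origin and of the missing class I or class II molecules also stay open, not tested apart from culture.

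Unfolded protein and integrated stress response genes averaged −0.90 in MHC-II KO against wild-type libraries with poly dI:dC (pooled SD 0.055). Library-size scaling gave −0.99, with TMM factors again too alike for a test. A trend with GC content or length is argued against by −0.81 after its removal, and replicate 3 of the MHC-II KO alone by −0.87 without it. MHC-I KO libraries, which have class II transcripts, averaged 5.84 ± 0.07 against 6.08 ± 0.06 in wild-type with poly dI:dC (SD, n = 3), a list not called there. Culture, sort day, strain of origin and the missing class II molecules stay open here too and were not tested.

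Each comparison of 2 groups has only 10 splits of its 6 libraries, which cannot give a share under 0.05, and the real split alone reached its own count (1 of 10). The real counts and the highest of the other splits were 5396 and 0, 5714 and 0, and 16 and 0 in wild-type cells with poly dI:dC, with αCD40 added, and between these treatments. In MHC-I KO cells they were 7581 and 0, 7478 and 0, and 35 and 8, and in MHC-II KO cells 6985 and 2, 7196 and 1, and 31 and 2. At rest, with poly dI:dC and with αCD40 they were 572 and 2, 3952 and 1, and 3542 and 0 for MHC-I KO against wild-type, 1205 and 5, 1438 and 0, and 1378 and 0 for MHC-II KO against wild-type, and 1114 and 5, 2631 and 6, and 2195 and 2 between the knockouts.

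For the interactions 100 splits were drawn, the real one included. The splits with the highest counts exchanged all 3 libraries between genotypes in 1 treatment and 0 in the other. Such a split adds the genotype differences of both treatments, so these splits are not a set without an interaction and decide nothing about chance. As values, 2 of 100 gave as many genes as the real 887 for the response of the MHC-II KO to poly dI:dC (highest other 1709), and 9 of 100 as many as the real 1852 for the MHC-I KO (highest other 3206). For adding αCD40 the real count in edgeR was 0 in both knockouts (663 and 635 genes at an unadjusted p under 0.05). Any split reaches 0, so 100 of 100 was fixed beforehand, with highest others of 5363 and 2570.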

How the results depend on the processing

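Scaling by library size alone, and list counts and list tests with a library or genes left out, were chosen after seeing the data. The counts of called genes stayed within 1.5 times in all 22 comparisons with median-of-ratios factors, library-size scaling, a minimum of 1 CPM and the replicate block. They moved further in 5 with no filter on low counts, 5 with DESeq2 and 3 with only the compared groups, while with 1 library left out 14 counts moved further and 142 did not. The causes were not tested.

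For adding αCD40 to poly dI:dC, the 16 genes in wild-type cells became 38 with no filter, 28 with only the compared groups, 42 with DESeq2 and 8 to 13 with 1 library left out. The 35 in MHC-I KO cells became 64, 8, 60 and 11 to 32. The 31 in MHC-II KO cells became 91 with no filter, 98 with DESeq2 and 15 to 39 with 1 library left out. The interactions with αCD40, at 0 in edgeR (663 genes at an unadjusted p under 0.05 for the MHC-I KO and 635 for the MHC-II KO), became 19 with no filter, 1 with DESeq2 and 0 to 6 with 1 library left out for the MHC-I KO, and 26, 12 and 0 to 1 for the MHC-II KO. The 1114 genes between the unstimulated knockouts became 694 with only these groups fitted.

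Near the H2 locus, a window of 20 Mb gave odds ratios of 1.55 for the unstimulated MHC-I KO, 1.38 for the unstimulated MHC-II KO and 1.35 for the MHC-II KO with αCD40 (exact adjusted p = 0.0738 each). Chromosome 17 as a whole gave 1.23, 1.33 and 1.32 (exact adjusted p = 0.374, 0.0753 and 0.0753). A window of 5 Mb gave 2.15 at rest and 1.57 with αCD40 between the knockouts, both then called, and without the targeted genes 1.75 and 1.37 (unadjusted exact p = 0.0118 and 0.0793).

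With library-size scaling some called log2 fold changes against unstimulated cells reversed. With poly dI:dC these were Atp5f1a in wild-type (−0.089), MHC-I KO (−0.23) and MHC-II KO cells (−0.16), Tcf4 in wild-type (−0.013) and Atp5f1b in MHC-I KO cells (−0.08). With αCD40 added they were Atp5f1a in the 3 genotypes (−0.13, −0.21 and −0.18), Uqcrfs1 in wild-type (−0.022), Atp5f1b (−0.061) and Cox4i1 (−0.22) in MHC-I KO, and Cox6c (−0.046) and Ighm (−0.11) in MHC-II KO cells. The whole scale moves there, which is the construction of this setting. The interactions of H2-Eb1 and H2-Aa in the MHC-II KO ranged from −0.62 to 6.374 and from −0.51 to 6.369, lowest without its replicate 3 with poly dI:dC.

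Replicate numbers did not pair the libraries. Deviations of same-numbered libraries had a mean correlation of −0.000635, 18 of 108 pairs were over 0.1, and 10 of 27 libraries correlated best with their own number. With the replicate block the counts were 5323 for poly dI:dC in wild-type cells, 14 for adding αCD40, 556 and 1133 for the unstimulated MHC-I and MHC-II KO against wild-type, and 1784 and 828 for the interactions with poly dI:dC. The block ended 2 of the list calls, class I processing with αCD40 in wild-type cells (adjusted p = 0.0511) and cDC2 markers in the MHC-II KO with poly dI:dC (0.059). Of 528 list tests, 41 calls were lost with an estimated correlation. Without the deleted genes 5 of 8 calls were lost in the 22 tests of lists that hold them, and 2 were gained. Without genes of more than 1 list 13 of 141 calls were lost and 3 gained in 198 tests. The lost calls of inhibitory ligands were MHC-II KO against wild-type with poly dI:dC (0.0851), with αCD40 (0.0528) and in the interaction (0.0668). Low counts limit the genes near 0, such as the deleted ones.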

Other observations

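The tests of Btnl2 given here were chosen only after its values were seen. Further lists differed in the responses of the knockouts to poly dI:dC. In the MHC-II KO the response was larger than in wild-type cells for nucleic acid sensors (12 of 24 positive, 2 negative; limma camera adjusted p = 3.85e-10), for apoptosis and survival genes (11 of 26 positive, none negative; 14 and 1 adjusted over the list alone, 1.24e-08) and for cholesterol synthesis (8 of 20 positive, none negative; 9 adjusted over the list alone, 4.3e-05). In the MHC-I KO it was larger for apoptosis and survival genes (10 of 26 positive, 1 negative; 8.92e-05), inhibitory ligands (7 of 17 positive, none negative; 0.00021) and nucleic acid sensors (7 of 24 positive, 2 negative; 11 and 3 adjusted over the list alone, 0.00248, with 3 positive and 4 negative under library-size scaling). Class I processing and loading genes were higher in the MHC-I KO than in the MHC-II KO in 9 of 18 at rest, 13 with poly dI:dC and 13 with αCD40 added, with none lower (1.68e-06, 3.97e-09 and 2.09e-10).

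Btnl2 stood at 194 CPM in unstimulated MHC-II KO cells (201.6, 199.7 and 180.8 CPM by library), against 0.3 CPM in wild-type. A variant near the H2 locus that both knockout strains carry from their embryonic stem cells is argued against by 0.118 CPM in unstimulated MHC-I KO cells, 1650-fold lower. A hypothesis is that Btnl2 transcription may follow class II regulatory sequence left beside it by the deletion: Btnl2 in MHC-II KO cells rose with poly dI:dC by 0.59 ± 0.20 (edgeR adjusted p = 0.0172) and H2-Ab1 in wild-type cells by 0.60 ± 0.15 (0.00154), a difference of −0.009 ± 0.252. That interval is wide, and Cd74 in MHC-II KO cells rose by 0.87 ± 0.06, so a like response is not specific to this sequence. Whether transcripts join sequence across the deletion was not analysed here.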
